A study of Homo sapiens with 12 samples.

How the data were processed

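The data are probe set signals from 12 Affymetrix oligonucleotide arrays, a 1-colour platform, hybridised with RNA of human primary epithelial cells. The tissue of origin is not given in the labels. Arrays were grouped by the labels into vehicle control, coarse, fine and ultrafine particles, with 3 arrays per group and 1 per numbered experiment. The series text calls the experiments biological replicates, and whether they came from separate donors is not given in the sources used here.

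The deposited values are signal intensity on a linear scale, made with GCOS per the submitters' processing notes. Its version and settings are not given in the sources used here. The 2%-trimmed mean of each array was 500.2, computed from the values, so each array appears to have been scaled by a single factor. Median signals were 159 to 181. The ratio of 3′ to 5′ GAPDH control signals ranged from 0.786 to 1.056. The 18S ribosomal RNA control signal ranged from 7480 to 39842, with geometric means of 20870 in control, 36310 in coarse, 19870 in fine and 15150 in ultrafine arrays. The 28S ribosomal RNA control signal ranged from 2344 to 29964 and was not used as a covariate. The number of arrays limits the precision.

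Of 22283 probe sets, 68 array controls were left out. Values were transformed as log2(value + 16), so fold changes are on that scale and understate the change of dim genes. The 60% of probe sets with the highest mean over all arrays were kept, which gave 13329. The annotation table gave 1 gene symbol for 19065 probe sets, several for 1043 and none for 2107, which are unnamed here. Entrez identifiers of 19053 of the probe sets with 1 symbol were found in the gene table, and 0 changed symbol. Genes were named only from probe sets with 1 symbol. Probe sets ending in _x_at or _s_at can detect related transcripts. No reference genome was used here.

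Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend of variance with mean) in a fit of all 12 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05. The experiment number was not in this fit, and a second fit had it as a block. The labels number the experiments in every group. Deviations from the group means correlated at 0.335 to 0.456 in the 18 pairs of arrays with the same number and at -0.286 to -0.115 in the 36 other pairs across groups, and 12 of 12 arrays were closest to one of their own number. The numbers therefore pair the arrays, and results with the experiments paired stand beside the unpaired ones. The median residual SD was 0.353 unpaired and 0.271 paired. Errors of genes are the SD of the log2 differences of the 3 experiments.

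Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation as an alternative, using 1 probe set per gene. Of 25 lists (19 of pathways and 6 of cell types), 22 had at least 5 tested members. NQO1 belongs to both the aryl hydrocarbon receptor and NRF2 lists, and SLC7A11 to the NRF2 and unfolded protein lists. List members were also counted adjusted over the list alone. The comparisons, lists, 21 preset genes (18 of them tested) and rule for naming genes were fixed before the data were examined. The rule took up to 12 genes per direction (6 between fractions) with the largest change among those passing without pairing and on 1 side of the control mean in every array. Where fewer than 10 passed, it used the paired fit. Preset genes were added, and up to 4 members per list as examples.

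Alternatives were the block, quantile normalization, a common median, pseudocounts of 1 and 64, no filter, the 40% brightest probe sets, no variance trend, array weights, only the 6 arrays compared, the mean of a gene's probe sets, and each array left out. Alternatives to the paired fit, including the 18S signal as a covariate and each experiment left out, were added after the data were seen.

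The scripts were tested on simulated data for coarse against control, with 13329 probe sets and 5 simulations. Without pairing, 0% of 1.5-fold, 14.6% of 2-fold and 72.1% of 4-fold changes were recovered, and with pairing 21.8%, 54.3% and 91.2%. False calls were 0% and 5.92% of calls. An NRF2 list shifted by 0.5 was called in 5 of 5 simulations, and 0 of 105 other lists were. The simulated noise was independent between probe sets, so these list results do not cover lists of correlated genes. In the arrays the estimated correlation was 0.249 for the NRF2 list and 0.411 for the NF-kB list. It was larger for others, at 0.443 for the mitotic, 0.626 for the metallothionein and zinc, and 0.95 for the squamous list. Unchanged groups against shared controls were simulated 100 times. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.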

Results

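Gene expression was measured on 12 Affymetrix oligonucleotide arrays hybridised with RNA from human primary epithelial cells. The cells had been cultured for 6 h with vehicle or with the coarse, fine or ultrafine size fraction of Chapel Hill particulate matter, each at 250 µg/ml. Each of the 4 groups held 3 arrays, 1 from each of 3 numbered experiments. The question was how the cells respond to each size fraction and whether the fractions differ at a matched mass dose. The deposited signal intensities had medians of 159 to 181 per array, and 13329 probe sets entered the tests. The number of arrays limits the precision of every value.

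The cultures carried high signal for keratins and adhesion proteins of basal epithelial cells. KRT5 had a mean signal of 59400 and KRT14 of 40400, which lay at the 99.7th percentile of all probe sets. The basal marker NGFR had 20.4. Leukocyte markers ranged from 8.04 (NKG7) to 208 (FCER1G), with PTPRC at 26.9, and endothelial markers from 5.59 (TIE1) to 196 (PECAM1). Fibroblast markers ranged from 3.92 (LUM) to 882 (COL1A1), with ACTA2 at 603 and COL1A2 at 70.5. Secretory markers ranged from 18.1 (LTF) to 7790 (SLPI), with MUC5AC at 172 and SCGB1A1 at 57.1. Of the leukocyte, endothelial and ciliated cell lists, only 2, 2 and 3 members passed the brightness filter, so these lists were not tested. The basal, secretory and fibroblast marker lists were not called in any particle group. Their adjusted p values in camera were 0.553, 0.436 and 0.39 for coarse, 0.745, 0.867 and 0.745 for fine, and 0.405, 0.841 and 0.75 for ultrafine particles. The secretory list with fine particles had a positive median and mean (0.119 and 0.0497) while its test pointed down.

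The genes with the largest rises after coarse particles were ARTN, CYP1A1, CYP1B1, CCL20 and IL36G. These calls come from the fit with the experiments paired, in which the experiment number is a block. The largest rise was in ARTN, which encodes the neurotrophic factor artemin, at 3.66 ± 0.217 on the log2 scale (SD over experiments, n = 3) or 12.7-fold. CYP1A1 and CYP1B1, cytochrome P450 enzymes under control of the aryl hydrocarbon receptor, rose by 3.36 ± 1.28 and 3.17 ± 1.32. CCL20, a chemokine, rose by 2.84 ± 1.64, the interleukin-1 family cytokine IL36G by 2.69 ± 1.01, and PTGS2, the inducible cyclooxygenase, by 2.29 ± 0.57. SLC7A11, the cystine transporter subunit, rose by 2.33 ± 0.507 (adjusted p = 4.89e-05) and TXNRD1, thioredoxin reductase, by 1.89 ± 0.573. The remaining members of the 12 largest rises were PLAT, PPP1R15A, THBD and PLAUR, at 3.73-, 3.2-, 3.17- and 2.68-fold. PLAT encodes tissue plasminogen activator and PLAUR the urokinase receptor.

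The largest fall with coarse particles was smaller than the largest rise. ADD2, which encodes an adducin of the membrane skeleton, fell by 1.79 ± 0.668 on the log2 scale. TXNIP, the thioredoxin-interacting protein, fell by 1.07 ± 0.688, and the Notch ligand JAG2, the growth factor PDGFC and the formin FHOD1 fell by 1.03 ± 0.197, 1.03 ± 0.186 and 1.04 ± 0.22. SLC6A8, DUSP4, DDIT4, SH3BP4 and CAMK2N1 fell by 0.92, 0.915, 0.889, 0.643 and 0.625.

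Across the lists fixed in advance, camera called 12 of 22 for coarse particles. The aryl hydrocarbon receptor list rose, with a median log2 change of 0.676 over 8 members (adjusted p = 1.41e-07, and 0.0189 with an estimated correlation). With the experiments paired, 4 of its members passed over all probe sets and 6 adjusted over the list alone, among them ALDH1A3 at 1.05 ± 0.587 and NQO1, a quinone reductase, at 0.6 ± 0.098. The list of NRF2 antioxidant targets rose with a median of 0.569 over 22 members (adjusted p = 1.38e-15, and 0.0444 with an estimated correlation). With the experiments paired, 6 of these passed and 16 adjusted over the list alone, including OSGIN1 at 1.35 ± 0.469 and the glutamate-cysteine ligase subunit GCLM at 1.21 ± 0.729. HMOX1, heme oxygenase 1, stood at 1.6 ± 0.621 with coarse particles and did not pass (adjusted p = 1 unpaired and 0.0702 paired).

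Genes of cholesterol synthesis also rose as a list with coarse particles, with a median of 0.621 over 16 members (adjusted p = 3.67e-13, and 0.0333 with an estimated correlation). Of these, 7 passed with the experiments paired and 11 adjusted over the list alone. In that fit INSIG1, a sterol-regulated membrane protein, rose by 1.28 ± 0.673, and the pathway enzymes IDI1, HMGCS1 and MSMO1 by 1.10 ± 0.08, 1.08 ± 0.409 and 0.858 ± 0.169. The NF-kB inflammatory list had a median of 0.767 over 18 members (adjusted p = 2.77e-06). This call was lost with an estimated correlation (adjusted p = 0.319) and held with the experiments paired (adjusted p = 0.0146 with an estimated correlation). Its passing members with the experiments paired were 4 over all probe sets and 10 adjusted over the list alone, with IL1A at 1.08 ± 0.413 and IER3 at 0.813 ± 0.386 beside CCL20 and PTGS2. CXCL8 stood at 2.07 ± 2.07, higher in 2 of 3 experiments, and did not pass (adjusted p = 0.308 paired).

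The unfolded protein and amino acid stress list rose with coarse particles at a median of 0.275 over 21 members (adjusted p = 0.000871, and 0.0461 with an estimated correlation, or 0.11 with pairing and an estimated correlation). With the experiments paired, 3 members rose and 1, DDIT4, fell, and adjusted over the list alone these were 6 and 1. DNA replication and mitotic genes were lower as lists, with medians of -0.468 and -0.189 (adjusted p = 9.46e-08 and 0.0249), and both calls were lost with an estimated correlation (adjusted p = 0.272 and 0.586). Without the coarse array of experiment 1 the mitotic list turned to the opposite direction and was not called (adjusted p = 0.856). None of their members passed over all probe sets, and adjusted over the list alone 4 DNA replication genes were lower with the experiments paired. The immediate early, matrix protease, autophagy and oxidative phosphorylation lists were called higher at adjusted p values of 0.0132, 0.0283, 0.0287 and 0.0249, and with an estimated correlation these adjusted p values were 0.401, 0.319, 0.408 and 0.408. Squamous differentiation genes were called only with the experiments paired (adjusted p = 8.45e-06, and 0.266 with an estimated correlation), where the elastase inhibitor PI3 rose by 0.935 ± 0.466.

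In the limma fit without pairing, coarse particles called 0 probe sets, with 522 at an unadjusted p under 0.05. With the experiments paired it called 93 probe sets, 76 higher and 17 lower, which name 61 genes. The paired count was 1 (SLC7A11, chosen after its value was seen) when the variance was not allowed to follow the mean signal. It was 30 without experiment 2 and 33 without experiment 3, and without pairing 1 probe set was called when the coarse array of experiment 2 was left out. Of the 22 named genes, 12, 11 and 9 passed without experiment 1, 2 and 3, 15 without the brightness filter and 15 with the 18S ribosomal RNA signal as a covariate, where CCL20 stood at 2.80 (adjusted p = 0.0895).

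Fine particles raised antioxidant and xenobiotic metabolism genes. HMOX1 rose by 5.44 ± 1.49 on the log2 scale (SD over experiments, n = 3), 43.3-fold, from a mean signal of 166 to 7890 (adjusted p = 0.00111 unpaired). SLC7A11 rose by 3.68 ± 0.258 and TXNRD1 by 2.76 ± 0.167 (adjusted p = 0.00217 and 0.002 unpaired). CYP1B1 rose by 3.51 ± 0.929 (adjusted p = 0.0309 unpaired). The remaining named rises passed only with the experiments paired. CYP1A1, ARTN and PTGS2 rose by 3.41 ± 0.717, 2.94 ± 0.441 and 2.60 ± 0.517. AKR1C1, an aldo-keto reductase whose near-identical relatives make the measurement uncertain, stood at 2.63 ± 1.99 on a dim probe set with a control signal of 32.9. A second, bright probe set of AKR1C1 rose by 1.64 (adjusted p = 0.0259 unpaired). The autophagy receptor SQSTM1 rose by 2.31 ± 0.648 and on another probe set by 0.926, NAV3 by 2.25 ± 0.744, the interleukin-13 receptor IL13RA2 by 2.19 ± 1.41 and OSGIN1 by 2.11 ± 0.42.

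EPN3, which encodes an epsin, fell by 2.09 ± 0.491 from a mean signal of 325 to 64, and the ubiquitin ligase gene RNF41 fell by 2.02 ± 0.655 from 171 to 30.1. PDK1, a pyruvate dehydrogenase kinase, fell by 2.01 ± 1.35, and the replicative helicase subunit MCM4 fell by 1.87 ± 0.904. SAC3D1, MYCBP2, KLHL36, PXMP2, BTBD2, DNASE1L1, PIGV and SEMA5A fell by between 1.68 and 1.87. All 12 passed only with the experiments paired, and none had a mean signal above 118 with fine particles.

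The NRF2 list rose with fine particles at a median of 1.09, with 22 of 22 members above 0 (adjusted p = 5.68e-25, and 0.0169 with an estimated correlation). Of its members, 5 passed without pairing and 13 adjusted over the list alone, and with the experiments paired these counts were 14 and 18. The aryl hydrocarbon receptor list rose at a median of 0.823 (adjusted p = 7.57e-06, and 0.0169 with an estimated correlation), with 6 of 8 members passing in the paired fit, such as ALDH3A1 at 0.897 ± 0.271. The unfolded protein and amino acid stress list rose at a median of 0.462 (adjusted p = 1.48e-05, and 0.0169 with an estimated correlation, or 0.0597 with pairing and an estimated correlation). Its members moved both ways with the experiments paired, since the phosphatase subunit PPP1R15A (a second probe set) rose by 1.6 ± 0.264 and the chaperone DNAJB9 by 1.22 ± 0.308 while DDIT4, an inhibitor of mTOR, fell by 1.27 ± 0.188.

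Cholesterol genes had a median of 0.397 with fine particles (adjusted p = 8.78e-07, and 0.106 with an estimated correlation, or 0.00829 with pairing and an estimated correlation). The members named here passed only with the experiments paired. INSIG1 rose by 1.55 ± 0.651 and the cholesterol transporter NPC1 by 1.3 ± 0.515. The NF-kB list had a median of 0.335 (adjusted p = 0.0391, and 0.582 with an estimated correlation), and IL1A and IER3 rose by 1.11 ± 0.495 and 0.731 ± 0.403. The growth factor EREG and the AP-1 subunit FOSL1 rose by 1.35 ± 0.647 and 1.32 ± 0.308 within the immediate early list (adjusted p = 0.00683, and 0.303 with an estimated correlation). DNA replication and mitotic lists were lower, at medians of -0.672 and -0.322 (adjusted p = 2.06e-08 and 2.1e-05, and 0.225 and 0.303 with an estimated correlation). MCM3 and RFC3 fell by 0.748 ± 0.292 and 0.855 ± 0.236, and the cyclin CCNB2 fell by 0.745 ± 0.154.

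The hypoxia and glycolysis list was lower with fine particles (median -0.293, adjusted p = 0.00866, and 0.303 with an estimated correlation), although VEGFA rose by 0.924 ± 0.019 with the experiments paired. The matrix protease and autophagy lists were called higher at adjusted p values of 0.0494 and 0.0198, and both were at 0.303 with an estimated correlation. The collagenase MMP1 rose by 1.03 ± 0.496 and the lysosomal galactosidase GLA by 0.902 ± 0.046 with the experiments paired. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 1.16 ± 0.089 in the same fit, while the list of p53 targets to which it belongs was not called (adjusted p = 0.22).

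Without pairing, fine particles called 9 probe sets, all higher, which name 7 genes. With the experiments paired they called 247, of which 145 were higher and 102 lower, and shifting every array to a common median turned this split to 112 higher and 150 lower. The unpaired count was 4, 5 or 4 without the control array of experiment 1, 2 or 3 and 4 without the variance trend, and the paired count was 39 without that trend and 69 or 63 without experiment 2 or 3. Of the 24 named genes, 8 passed without the trend in the paired fit, 13 without the brightness filter, 18 with a pseudocount of 1, and 14, 10 and 8 without experiment 1, 2 and 3.

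Ultrafine particles gave the largest rise of HMOX1, by 6.21 ± 0.843 on the log2 scale (SD over experiments, n = 3) or 74.1-fold, to a mean signal of 13500 (adjusted p = 0.000237). All 12 genes named for this comparison passed without pairing. SLC7A11 rose by 4.02 ± 0.421, TXNRD1 by 3.32 ± 0.43, CYP1B1 by 3.28 ± 1.01 and OSGIN1 by 2.86 ± 0.145. GCLM and GCLC, the subunits of the enzyme that starts glutathione synthesis, rose by 2.73 ± 0.29 and 2.11 ± 0.341. SLC30A1, a zinc exporter, rose by 1.97 ± 0.244 (adjusted p = 0.00825). PPIF, a mitochondrial cyclophilin, rose by 1.65 ± 0.552 and the small GTPase RIT1 by 1.37 ± 0.371. AKR1C2 and AKR1C1 rose by 1.96 ± 0.303 and 1.64 ± 0.349 on bright probe sets that can detect several aldo-keto reductases. The dim probe set of AKR1C1 that was named for fine particles stood at 3.41 with ultrafine particles (adjusted p = 0.00768 paired).

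The NRF2 list rose with ultrafine particles at a median of 1.21, with 22 of 22 members above 0 (adjusted p = 7.9e-40, and 0.00616 with an estimated correlation). Of its members, 8 passed without pairing, 16 adjusted over the list alone, and 17 over all probe sets with the experiments paired. The unfolded protein and amino acid stress list rose at a median of 0.54 and the aryl hydrocarbon receptor list at 0.584 (adjusted p = 3.96e-08 and 4.97e-07, and 0.00616 and 0.00816 with an estimated correlation). CYP1A1 rose by 3.13 ± 0.846, PTGS2 by 2.82 ± 1.02 and PPP1R15A (the second probe set) by 1.73 ± 0.541 with the experiments paired. DNAJB9 rose by 1.29 ± 0.412, CDKN1A by 1.18 ± 0.272 and the stress cytokine GDF15 by 1.63 ± 0.999 in the same fit.

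The cholesterol list was called higher with ultrafine particles (median 0.313, adjusted p = 2.5e-05, and 0.148 with an estimated correlation, or 0.0214 with pairing and an estimated correlation). The heat shock, immediate early and autophagy lists were called higher at adjusted p values of 0.00484, 0.00503 and 0.000111, and at 0.148, 0.292 and 0.148 with an estimated correlation. Within the immediate early list, in the paired fit, FOSL1 and EREG rose by 1.5 ± 0.186 and 1.43 ± 0.149 while FOS fell by 2.28 ± 0.276. DNA replication and mitotic genes were lower at medians of -0.606 and -0.37 (adjusted p = 4.76e-09 and 3.74e-05, and 0.148 and 0.355 with an estimated correlation), with MCM2, RFC3 and MCM3 passing in the paired fit at -0.922, -0.873 and -0.759. The NF-kB list was not called (median 0.0182, adjusted p = 0.613).

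Lists that were called in no fraction without pairing had these adjusted p values in coarse, fine and ultrafine arrays. They were 0.436, 0.0974 and 0.841 for interferon response genes, 0.366, 0.22 and 0.139 for p53 targets, and 0.969, 0.745 and 0.894 for TGF-beta, BMP and YAP targets. Ribosomal protein genes stood at 0.337, 0.557 and 0.678, and squamous differentiation genes at 0.151, 0.745 and 0.75. The squamous list pointed up in each, and without the control array of experiment 3 it was called lower with fine and ultrafine particles (adjusted p = 0.0312 and 0.0288). The p53 targets had negative medians (-0.0829 and -0.0694) with coarse and ultrafine particles and positive means (0.117 and 0.243), with a test pointing up. Lists called in some fractions were not called in others, namely heat shock genes with coarse (0.366) and fine particles (0.745), and hypoxia genes with coarse (0.553) and ultrafine particles (0.205). Oxidative phosphorylation genes were not called with fine (0.164) or ultrafine particles (0.874), nor matrix proteases with ultrafine particles (0.405).

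Without pairing, ultrafine particles called 20 probe sets, all higher, which name 14 genes, and with the experiments paired 239, of which 161 were higher and 78 lower. The unpaired count was 9, 10 and 6 without the control array of experiment 2, the control array of experiment 3 and the ultrafine array of experiment 3, 8 without the variance trend and 13 with only the 6 arrays of both groups. The paired count was 55 without the trend and 104 or 64 without experiment 2 or 3, and 11 of the 12 named genes still passed without the trend in the paired fit, where RIT1 was at an adjusted p of 0.0526.

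The preset genes that passed in no particle group, paired or unpaired, were IL1B, IL6, CXCL8, ATF3, DDIT3, EGR1, DNAJB1, MT1X and MT2A. The cytokine IL1B stood at 1.06 ± 0.417, 0.971 ± 0.856 and 0.585 ± 0.532 with coarse, fine and ultrafine particles (adjusted p = 0.0631, 0.051 and 0.315 paired). IL6 stood at 0.183 ± 0.549, 0.384 ± 0.239 and 0.031 ± 0.538, and CXCL8 with fine and ultrafine particles at 1.56 ± 0.582 and 1.42 ± 1.37. The stress transcription factor genes ATF3 and DDIT3 stood at 1.27 ± 0.784, 1.01 ± 0.198 and 0.67 ± 1.43, and at -0.068 ± 0.242, 0.52 ± 0.46 and 0.412 ± 0.498. EGR1 stood at 0.392 ± 1.2, 0.856 ± 0.785 and -0.062 ± 0.383, and the chaperone gene DNAJB1 at 0.547 ± 0.199, 0.405 ± 0.237 and 0.408 ± 0.274. MT1X stood at -0.215 ± 0.396, 0.186 ± 0.148 and 0.204 ± 0.204, and MT2A at -0.111 ± 0.393, 0.165 ± 0.048 and 0.17 ± 0.152. In the paired fit NQO1 rose by 1.15 ± 0.048 and 1.23 ± 0.222 and HMGCS1 by 0.81 ± 0.312 and 0.83 ± 0.076 with fine and ultrafine particles, GCLM by 1.87 ± 0.421 with fine particles, and CDKN1A by 0.68 ± 0.257 with coarse particles.

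**Figure D1:**
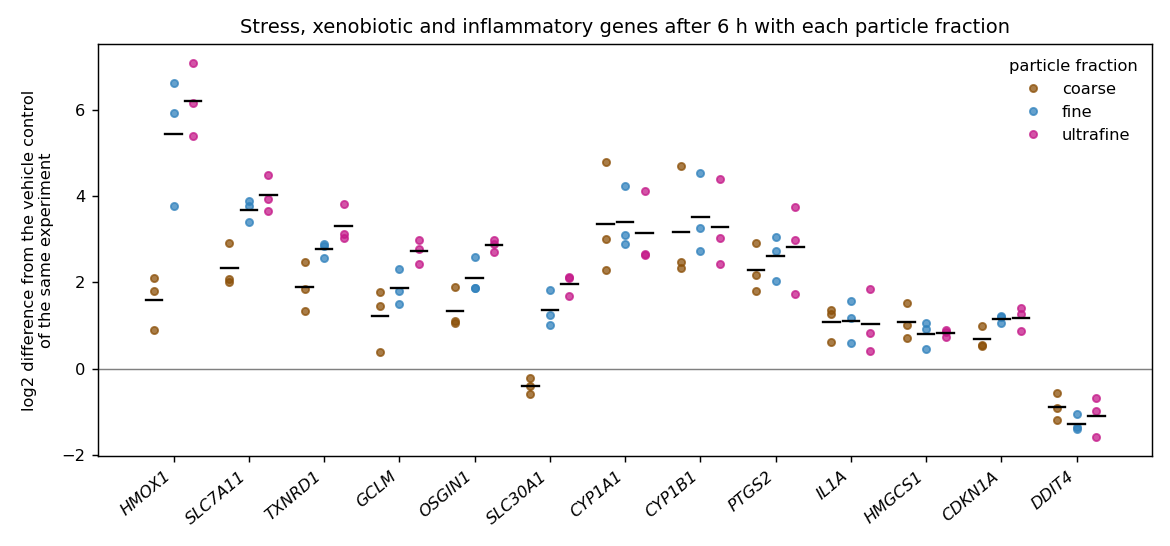
Log2 difference between particle and vehicle arrays of the same experiment (vertical axis) for 13 genes (horizontal axis). Each point is 1 of 3 experiments, colours are particle fractions and black bars are means. HMOX1 has means of 1.6, 5.44 and 6.21 in coarse, fine and ultrafine arrays, while CYP1A1 has 3.36, 3.41 and 3.13.

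With the 3 fractions pooled against vehicle, 18 probe sets were called without pairing, all higher, and 266 with the experiments paired, of which 177 were higher and 89 lower. A test of any difference among the 4 groups called 12 and 224. The pooled count was 10, 6 and 4 without the control array of experiment 1, 2 and 3 and 8 without the variance trend, and the 4-group count was 6 and 5 without the control array of experiment 2 and 3, 5 without the ultrafine array of experiment 2 or 3, and 5 without the trend. Paired, these counts were 106 and 68 without experiment 2, 114 and 66 without experiment 3, and 84 and 33 without the trend. In the paired fit, 50 probe sets naming 31 genes were called higher in every fraction, among them CYP1A1, CYP1B1, SLC7A11, TXNRD1, PTGS2, ARTN, HMGCS1 and CDKN1A. The 5 genes called lower in every fraction were DDIT4, JAG2, PDGFC, SH3BP4 and SLC6A8. Of the gene lists, 9 were called for pooled particles without pairing and 12 with it, and 4 in either fit with an estimated correlation, namely the aryl hydrocarbon receptor, NRF2, unfolded protein and cholesterol lists. Pairing added the heat shock, matrix protease and squamous lists, higher at adjusted p values of 0.048, 0.000285 and 0.00447 (0.2, 0.0503 and 0.397 unpaired), and with pairing and an estimated correlation these were 0.22, 0.104 and 0.464.

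The particle comparisons share their 3 control arrays, and the shared calls have to be read beside that. In the paired fit, coarse and fine shared 62 higher and 11 lower calls, against 0.827 and 0.13 for independent lists. Coarse and ultrafine shared 52 and 10 (0.918 and 0.0995 for independent lists), and fine and ultrafine 106 and 37 (1.75 and 0.597). No probe set was called in opposite directions in any pair, and unchanged groups simulated against the same controls shared 0.01, 0.01 and 0.02 calls on average. Unchanged groups give few calls of any kind, so this does not show how many real shared calls come from the controls. Fold changes correlated across probe sets at 0.526, 0.566 and 0.633 in that order, beside 0.501 for each simulated pair. The covariances were 0.0775, 0.0805 and 0.101, against simulated values of 0.0417, 0.0418 and 0.0418. With 3 control arrays no split leaves enough for a separate estimate, so part of the excess of shared calls over independent lists may come from the shared controls.

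The direct comparison asked whether coarse and ultrafine particles differ at the same mass dose. HMOX1 fell by 4.62 ± 0.337 on the log2 scale from ultrafine to coarse arrays (SD over experiments, n = 3), a 24.5-fold lower level, and SLC30A1 fell by 2.37 ± 0.298. Both passed without pairing, each at an adjusted p of 0.00458. With the experiments paired, SLC7A11 (a second probe set), GCLM, OSGIN1 and TXNRD1 were lower with coarse than with ultrafine particles at -1.92 ± 0.538, -1.52 ± 0.515, -1.52 ± 0.455 and -1.43 ± 0.307. ADD2 was lower at -1.65 ± 0.571. In the other direction, CCL20 was 3.34 ± 1.70 higher with coarse particles. The NF-kB pathway inhibitors TNFAIP3 and NFKBIA were 1.85 ± 0.965 and 1.47 ± 0.849 higher, and the chemokine CXCL1 was 1.62 ± 0.803 higher. TUBA1A and the nucleotide receptor P2RY2 were 1.18 ± 0.443 and 1.07 ± 0.426 higher. With the 18S ribosomal RNA signal as a covariate in the paired fit, 3 of the 12 genes with the largest differences passed, namely HMOX1, SLC30A1 and TNFAIP3. The others lost the call, with CCL20 at 3.28 (adjusted p = 0.175), CXCL1 at 1.99 (0.0696), NFKBIA at 1.58 (0.0936), TUBA1A at 1.23 (0.123), P2RY2 at 0.853 (0.415), SLC7A11 at -1.96 (0.0696), ADD2 at -1.61 (0.123), GCLM at -1.21 (0.0696) and OSGIN1 at -1.19 (0.118).

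**Figure D2:**
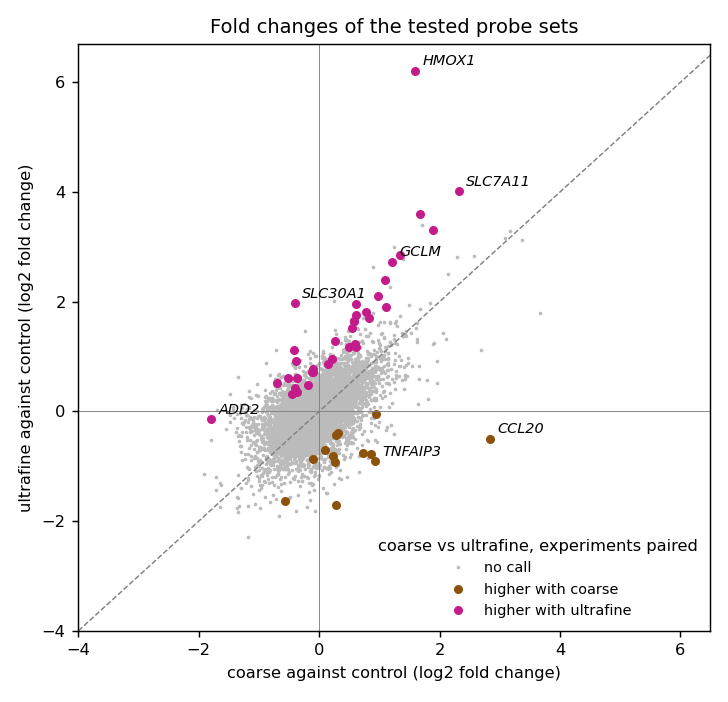
Log2 fold change against vehicle of each tested probe set with coarse (horizontal axis) and ultrafine (vertical axis) particles. Coloured points are probe sets called between coarse and ultrafine arrays with the experiments paired, and the dashed line marks equal changes. HMOX1 lies far above the line (1.6 and 6.21), and 13 called probe sets lie below it.

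As a list, NRF2 targets were lower with coarse than with ultrafine particles, with 22 of 22 members below 0 and a median of -0.665 (adjusted p = 1.14e-20, and 0.0599 with an estimated correlation, or 0.0155 with pairing and an estimated correlation). The metallothionein and zinc list was lower at a median of -0.642 (adjusted p = 1.62e-10, and 0.0957 with an estimated correlation). The NF-kB list was higher at a median of 0.45 (adjusted p = 0.000577, and 0.466 with an estimated correlation). Aryl hydrocarbon receptor targets were not called (adjusted p = 0.709), and the differences of CYP1A1 and CYP1B1 were 0.23 ± 0.518 and -0.114 ± 0.507. The unfolded protein list and the autophagy list were lower at adjusted p values of 0.00428 and 0.0482, and the cholesterol and mitotic lists were higher at 0.011 and 0.0482. With an estimated correlation these adjusted p values were 0.0957, 0.466, 0.466 and 0.703. Pairing added the heat shock list, lower at 0.0236, and the matrix protease, squamous and oxidative phosphorylation lists, higher at 0.0236, 0.00526 and 0.0281, which with an estimated correlation had adjusted p values of 0.26, 0.344, 0.436 and 0.26. Unpaired and without the ultrafine array of experiment 3, the squamous list was called lower (adjusted p = 0.0341). The 18S ribosomal RNA control signal was also higher in coarse than in ultrafine arrays, by 1.26 ± 0.742 on the log2 scale, in 3 of 3 experiments. The 28S signal did not follow this in every experiment. It was 26335, 13774 and 22941 in the coarse arrays of experiments 1, 2 and 3, and 5303, 25048 and 20351 in the ultrafine arrays. Without pairing 2 probe sets were called and with the experiments paired 49, of which 13 were higher and 36 lower with coarse particles. The paired count was 11 with the 18S signal as a covariate, 2 without the variance trend (HMOX1 and SLC30A1), and 16 or 8 without experiment 2 or 3, and 7, 4 and 4 of the 12 genes passed without experiment 1, 2 and 3.

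The metallothionein and zinc list was called in opposite directions in the fractions. It was called lower with coarse particles, with 0 of 7 members above 0 and a median of -0.343 (adjusted p = 0.0107, and 0.408 with an estimated correlation). It was called higher with fine particles at a median of 0.182 and with ultrafine particles at 0.314 (adjusted p = 0.0322 and 5.76e-05, and 0.517 and 0.213 with an estimated correlation). SLC30A1 stood at -0.398 ± 0.189 with coarse particles and did not pass, and rose by 1.35 ± 0.423 with fine particles in the paired fit. Against control no metallothionein passed over all probe sets, with MT1G at -0.376 ± 0.329 and 0.616 ± 0.243 in coarse and ultrafine arrays. Adjusted over the list alone, 1 member was lower with coarse, 1 higher with fine and 3 higher with ultrafine particles with the experiments paired. Between coarse and ultrafine arrays 3 of 7 members were lower in the paired fit, namely SLC30A1, MT1F and MT1G, and 5 adjusted over the list alone. Metallothionein probe sets can detect near-identical transcripts, so single members are uncertain, and MT2A had a signal of 65700 in controls.

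Coarse particles were also set against fine particles. HMOX1 stood at -3.84 ± 0.865 (coarse minus fine; adjusted p = 0.0508 unpaired and 0.000289 paired) and SLC30A1 at -1.75 ± 0.325. ADD2, SLC7A11, AKR1C2 and AKR1C1 (bright probe sets) were lower in the paired fit at -1.68 ± 0.706, -1.36 ± 0.368, -1.13 ± 0.295 and -1.06 ± 0.202. The NRF2 and metallothionein lists were lower with coarse particles (adjusted p = 2.43e-07 and 2.3e-05), and the oxidative phosphorylation list was higher (adjusted p = 0.000752), and each had an adjusted p of 0.456 with an estimated correlation. Pairing added the NF-kB, mitotic, hypoxia and squamous lists, higher at 0.0247, 0.0185, 0.0292 and 0.0242, and the unfolded protein list, lower at 0.0133, and with an estimated correlation these were 0.433, 0.478, 0.597, 0.642 and 0.433. The limma fit called 0 probe sets without pairing (753 at an unadjusted p under 0.05) and 8 with it, all lower with coarse particles. The paired count became 29, of which 20 were higher and 9 lower, when arrays were shifted to a common median, and 2 or 3 without experiment 2 or 3. Of the 6 named genes, HMOX1 and SLC30A1 still passed without the variance trend, ADD2 lost the call with the 18S covariate (-1.65, adjusted p = 0.137), and 4, 2 and 3 passed without experiment 1, 2 and 3. Without pairing, 1 probe set was called when any of the fine arrays was left out. The call was higher with coarse particles without the fine array of experiment 1 or 3, and lower without that of experiment 2.

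No probe set passed between fine and ultrafine particles. The limma fit called 0 probe sets without pairing and 0 with it, with 469 and 1057 at an unadjusted p under 0.05. HMOX1 stood at -0.775 ± 0.754 (fine minus ultrafine) and GCLM at -0.856 ± 0.37, each lower with fine particles in 3 of 3 experiments. As lists, NRF2 targets and heat shock genes were lower with fine particles (adjusted p = 0.00031 and 0.0017), and both calls were lost with an estimated correlation (adjusted p = 0.67 and 0.307). Pairing added the metallothionein list, lower with fine particles, and the NF-kB and matrix protease lists, higher, each at 0.0128, and with an estimated correlation these were 0.52, 0.418 and 0.419.

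**Figure D3:**
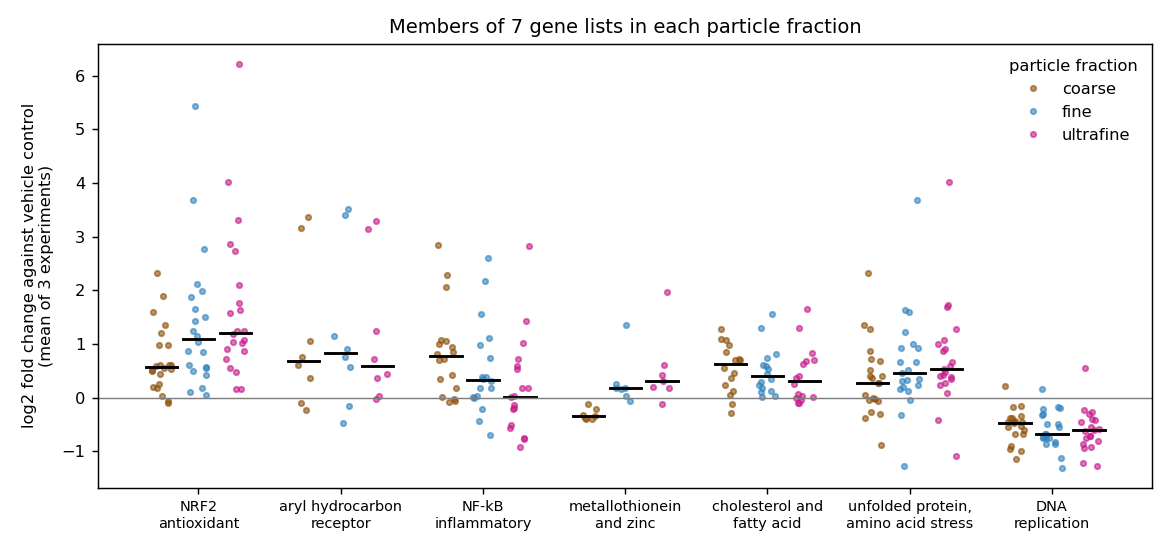
Log2 fold change against vehicle (vertical axis, mean of 3 experiments) of every tested member of 7 gene lists (horizontal axis). Points are genes, colours are particle fractions and black bars are medians. The NRF2 medians are 0.569, 1.09 and 1.21 in coarse, fine and ultrafine arrays, and those of the NF-kB list are 0.767, 0.335 and 0.0182.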

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

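The rule that selected the list results was set after the metallothionein result was known. The tests of a weaker overall response, of the list without SLC30A1 and of SLC30A1 itself, the intervals of list means, the estimated correlations beside the 18S signal and the reading of each list mean by its SE were chosen only after the results were seen.

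The metallothionein and zinc list differed between fractions, with a mean log2 difference of -0.610 for coarse minus fine and -0.823 for coarse minus ultrafine arrays, a call lost with an estimated correlation (adjusted p = 0.456 and 0.0957). With the 18S signal as a covariate in the paired fit the second was -0.907 (95% interval -1.39 to -0.422), which argues against ribosomal RNA signal as the whole cause, although camera lost the call there with an estimated correlation (adjusted p = 0.0956). Without SLC30A1 the mean was -0.565 (SE 0.248 unpaired; unadjusted p = 1.95e-07, and 0.04 with an estimated correlation), past its bound by barely more than its SE, which argues only weakly against that gene alone carrying the list, since the 95% interval was -1.14 to 0.00705 unpaired and -0.972 to -0.158 paired. Residuals of metallothionein probe sets correlated at a median of 0.779, as hybridisation among copies would give, but co-regulated genes could give this too, and the reading of this value was adjusted to the written prediction after it was seen. Copies do not explain SLC30A1, at -2.37 (SE 0.26, adjusted p = 0.00458), and a biological difference between the fractions was not tested.

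The NRF2 list was lower in coarse than in ultrafine arrays by a mean of -0.958, with -0.916, -0.954 and -1.01 in the experiments, a call lost unpaired with an estimated correlation (adjusted p = 0.0599, and 0.0155 paired). With the 18S covariate the mean was -0.842 (95% interval -1.08 to -0.601, adjusted p = 3.07e-24, and 0.0241 with an estimated correlation). This argues against the 18S signal as the whole cause. After quantile normalization it was -0.958 (95% interval -1.58 to -0.334 unpaired and -1.21 to -0.710 paired). The mean without the covariate was thus unchanged, which argues against scaling, although the unpaired interval reaches past the bound written in advance. A weaker overall response to coarse particles was predicted to lower the NF-kB list too. With ultrafine particles the NF-kB list was not called in camera (mean 0.193 against control, adjusted p = 0.613). It therefore had little room to be lower with coarse particles, and only a higher value bears on this. That list had a mean of 0.649 with an SE of 0.559 in the unpaired fit of this test (0.196 paired, 95% interval 0.169 to 1.13). Its call was lost with an estimated correlation (adjusted p = 0.466, and 0.0825 paired). Between these groups the aryl hydrocarbon receptor list was not called in camera (mean -0.0253, adjusted p = 0.709). The cholesterol list was higher and the unfolded protein and autophagy lists lower (means 0.132, -0.38 and -0.22), calls lost with an estimated correlation. Lists thus moved both ways, which argues only weakly against a response weaker in every list, while one weaker in some lists stays open. A biological difference between the fractions was not tested.

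The NF-kB list was higher in coarse than in ultrafine arrays, with experiment means of 0.197, 1.25 and 0.497 (SD 0.544), a call lost with an estimated correlation (adjusted p = 0.466, and 0.0825 paired). With the 18S covariate its mean was 0.785 (SE 0.24, 95% interval 0.169 to 1.40, adjusted p = 1.03e-07), against 0.649 without it. This argues only weakly against the 18S signal as the whole cause, since the interval reaches into the range written in advance for that cause. Camera also lost the call there with an estimated correlation (adjusted p = 0.0956). Whether a single experiment carries the difference cannot be told apart from a shared one, since the lowest mean was 0.197 and 3 experiments are too few.

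Among 8886 dim probe sets outside the tests, 2 were higher and 4 lower with fine particles and 2 higher and 5 lower with ultrafine particles in the paired fit, and with coarse particles limma called 0 in the paired fit (481 at an unadjusted p under 0.05). Each lay below the filter limit of 98.8 in at least 1 of the groups compared, so no fold is given. Named after their values were seen, the higher ones with fine particles were POU1F1, from a mean signal of 1.91 to 64.3 (adjusted p = 0.00803), and TLX3, from 8.82 to 64.2 (0.042). With ultrafine particles they were TRHDE, from 2.78 to 58.6 (0.0249), and a probe set without a listed gene, from 13.1 to 103.2 (0.0409). The lower ones with fine particles were FGFR2, TCAF1, TNS3 and CYP26B1, from 205.2, 51.5, 246.8 and 134.9 to 26.2, 3.66, 32.4 and 20.4. With ultrafine particles they were POLA1, BARD1, TNS3, CYP26B1 and a probe set without a listed gene, from 151.4, 205.5, 246.8, 134.9 and 78.1 to 24.3, 18.7, 37.1, 14.8 and 4.2.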

How the results depend on the processing

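All alternatives to the paired fit, including leaving out an experiment and the 18S covariate, were chosen only after the data were seen, and the others were planned.

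With the replicate block, 93, 247, 239, 8, 49, 266 and 224 probe sets were called for coarse, fine and ultrafine against control, coarse against fine, coarse against ultrafine, pooled particles and the 4-group test. List counts with the block were 8, 11 and 5 for coarse against fine, coarse against ultrafine and fine against ultrafine. Beyond the list calls given with the results the block changed no list call, and of 410 gene results 277 kept their side of the threshold with it while the others gained a call. Without the variance trend the unpaired counts were 4 for fine, 8 for ultrafine, 8 for pooled particles and 5 for the 4-group test. Array weights gave 1 for coarse against fine. Only the 6 arrays compared gave 13 for ultrafine and 1 for coarse against ultrafine. With an estimated correlation, camera called 4, 3, 3, 0, 0 and 0 lists for the 6 comparisons in order, and the mean of a gene's probe sets gave 4 for fine against ultrafine. The cause was not tested.

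With the replicate block and no trend, counts were 1, 39, 55, 4, 2, 84 and 33 in the order above. With the block and no filter they were 153 for fine, 5 for coarse against fine and 149 for the 4-group test, where more probe sets were tested. With the block and a common median they were 29 for coarse against fine and 1 for fine against ultrafine. With the block and the 18S covariate, coarse against ultrafine gave 11. The cause was not tested.

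Leaving out an array gave 0 to 1 probe sets for coarse, 4 to 9 for fine, 6 to 22 for ultrafine, 0 to 1 for coarse against fine, 2 to 3 for coarse against ultrafine, 0 to 0 for fine against ultrafine, 4 to 19 pooled and 5 to 15 for the 4-group test. Leaving out an experiment in the paired fit gave 30 to 108, 63 to 167, 64 to 178, 2 to 6, 8 to 38, 0 to 0, 106 to 232 and 66 to 174. List counts ranged over 8 to 13, 7 to 13, 9 to 13, 4 to 5, 4 to 9 and 1 to 7. The fine count of lists was 7 without control 2. Coarse against fine had 5 without fine 1, coarse 2 or coarse 3, and coarse against ultrafine had 4 without coarse 2. Fine against ultrafine had 7 without ultrafine 1, 4 without fine 2 or fine 3 and 1 without ultrafine 3.

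List results that reversed with a call in the main or the alternative setting all came from leaving out an array. The mitotic list with coarse particles had an adjusted p of 0.856 without coarse 1 (range 1.6e-05 to 0.856). The squamous list had 0.0312 with fine and 0.0288 with ultrafine particles without control 3 (ranges 0.00467 to 0.676 and 0.000314 to 0.662). It had 0.0341 for coarse against ultrafine without ultrafine 3 (0.000314 to 0.779) and 0.00928 for fine against ultrafine without fine 3 (0.00205 to 0.561). Of 6484 alternatives for 410 gene results, 6288 kept their side of the threshold, 47 lost the call, 149 gained it and 0 reversed. Reversal was counted only where the main or the alternative result was called, so uncalled results may have changed direction. Of 1716 alternatives for 132 list results, 1546 kept their side of the threshold, 98 lost the call, 67 gained it and 5 reversed. Uncalled in either fit, the heat shock and secretory lists with fine particles pointed down unpaired and up with the block. The same held for the aryl hydrocarbon receptor, squamous and secretory lists between fine and ultrafine arrays, and for the secretory list with pooled particles. Array precision is limited by 3 arrays per group, and dim probe sets by their signal.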

Other observations

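The families in this part were chosen only after other results were seen, and their tests were written before their own values.

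Proteasome subunit genes were higher with coarse particles, with 33 of 40 above 0 and a mean log2 change of 0.144 (adjusted p = 9.35e-07 in camera, and 0.086 with an estimated correlation). They were also higher than with fine and ultrafine particles (adjusted p = 4.32e-05 and 0.000189, and 0.166 and 0.0756 with an estimated correlation). Between coarse and ultrafine arrays, histone genes were higher and zinc finger genes named ZNF lower with coarse particles. Each had an adjusted p of 0.0161 in camera, and of 0.0756 with an estimated correlation. Histone genes had a mean of -0.325 with ultrafine particles, with 5 of 24 above 0, and of -0.207 with fine particles (adjusted p = 0.00266 and 0.0446, and 0.0664 and 0.218 with an estimated correlation). Without pairing no histone or proteasome member passed in limma. Paired, H2AZ1 stood at -0.55 with fine particles on 1 of its 2 probe sets (adjusted p = 0.0421, and 0.582 on the other) and H2BC12L at -0.69 with fine and -0.73 with ultrafine particles (adjusted p = 0.0417 and 0.0309), both named after their values were seen. The means given for these families kept their sign under quantile and common-median scaling.

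The hypothesis that further families move as a group with ultrafine particles was tested with camera. Proteasome subunits had an adjusted p of 0.359, aminoacyl-tRNA synthetases of 0.758 and zinc finger genes named ZNF of 0.196 against control. Their means were 0.0259, 0.00826 and 0.0464, so no such movement was called against control. The histone value of 0.00266 does not decide, since the call was lost with an estimated correlation.

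Other splits of the arrays were used to ask whether chance can be excluded. Each pair of groups has 10 splits, too few for a share under 0.05. Unpaired, the real counts were 0, 9 and 20 for coarse, fine and ultrafine against control, and the highest of the other splits gave 1, 0 and 1. For coarse against fine, coarse against ultrafine and fine against ultrafine the real counts were 0, 2 and 0 and the highest others 0, 0 and 1. As many calls as the real split came from 10, 1 and 1 splits against control and from 10, 1 and 10 between fractions. Paired, the real counts were 93, 247, 239, 8, 49 and 0, the highest others 1, 0, 1, 0, 0 and 0, and splits as large 1, 1, 1, 1, 1 and 10. Only 4 of the 10 splits part all 3 pairs, and the other splits gave 0 to 1 calls.

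For pooled particles without pairing, 3 of 100 splits gave at least the real 18 calls, and the highest other gave 63. Setting 3 arrays of experiment 3 as control gave 63 and 3 of experiment 2 gave 34, which points to a structure of the arrays by experiment. Within experiments, 1 of 64 splits reached the real 266 and the highest other gave 64, which makes chance unlikely there without excluding it. For the 4-group test without pairing, 2 of 100 splits reached the real 12, namely the real split and another that also gave 12. These splits ignore the experiments, so they cannot exclude chance. Paired, 1 of 100 reached 224, with a highest other of 121, which makes chance unlikely.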
